A study of Mus musculus with 9 samples.

How the data were processed

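Poly(A) RNA of mouse testis was sequenced from 9 samples in 3 groups of 3, labelled Vehicle, BU+PBS and BU+BTT-3033. The authors deposited 1 table of whole-number counts per gene symbol for all 9 libraries, with no normalization, and its columns were matched to the samples by name. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1 and StringTie 2.2.1 and the mouse build GRCm38; which step each tool performed, the strand setting and the annotation are not given in the sources used here. Per the labels' protocols, mRNA was captured on oligo(dT) beads and cDNA was primed with random oligonucleotides. In every library the count 3 was commoner than the counts 1 and 2, so the deposited counts may be rounded from an estimate rather than tallied read by read. The labels speak of samples of mice and do not say that each sample came from its own animal, so p-values measure the spread between these samples, part of which could be technical. No replicate pair of a group was as close as sampling noise allows: the smallest chi-square per degree of freedom, over genes with a pair sum of at least 20 counts, was 5.15, between Vehicle replicates 1 and 3.

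The table lists 39236 gene symbols. Genes were kept by edgeR's filterByExpr with the 3 groups, which left 24894 and removed 14342. Counts were scaled by trimmed mean of M-values (TMM) and fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by the robust quasi-likelihood method, with all 9 libraries in 1 fit and 1 mean per group. All 3 pairwise contrasts were tested, with Benjamini-Hochberg adjustment within each, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes are those of this test. Levels are CPM from edgeR's cpm function after TMM scaling, as mean ± SD over 3 libraries. The standard error (SE) given with a log2 fold change is its absolute value divided by the square root of the test's F statistic. It is thus derived from the test and is not a separate estimate of the uncertainty of the fold. Total counts per library ranged from 41464437 to 50965210. So 3 counts, taken as the floor for a gene at 0, are worth 0.0547 CPM in BU+PBS, 0.0869 CPM in Vehicle and 0.0572 CPM in BU+BTT-3033, as the mean over the libraries of a group. A fold against a group at 0 in all libraries is given as a lower bound from that floor, and a fold against 1 to 3 counts with its 95% exact interval. Floors and intervals cover counting error only.

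Of 29 gene lists, fixed before the data were examined, 28 had at least 5 tested members: 531 of their 536 symbols are in the table, 1 of them under an older name. Each list was tested with camera (inter-gene correlation 0.01), adjusted over all lists and the 3 comparisons, and again with the correlation estimated from the data and with fry. A list's median log2 fold change is given minus that of all tested genes. Genes to be named were also fixed before the data were examined. They are Itga2 and Itgb1; the 8 genes with the largest change in each direction among those called, with a mean of at least 5 CPM, no overlap between the groups and no clone or predicted name; and up to 3 members per list with the smallest p, or the most abundant member where none was called. Genes named outside this rule are said to be so. Positions are from GENCODE M21 on GRCm38, in which 24257 tested symbols (97.4%) matched 1 gene.

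The replicate numbers of the labels were tested for pairing across groups. Fold changes of BU+BTT-3033 against BU+PBS and of BU+PBS against Vehicle share the BU+PBS libraries. Their correlation was therefore set beside 20 simulations of unchanged groups, all at the BU+PBS mean levels, with genes drawn independently. Alternatives fixed before the data were examined were 3 other scalings (DESeq2 size factors, library size, and a common median of the Sertoli cell list), the DESeq2 1.42.0 Wald test, limma voom with sample weights, no low-count filter, at least 1 CPM in 3 libraries, a 2-fold minimum, the 6 compared samples alone, a replicate block, non-robust dispersions and leaving out each library; an adjusted p under 0.1 was added after the data were seen. Annotation and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

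The fit was tested on simulated counts of 24894 genes, with 50 genes changed at each of 4 fold sizes. When every group had the spread of Vehicle, 4-fold changes were recovered for 92% of genes in BU+PBS against Vehicle, 78% in BU+BTT-3033 against BU+PBS and 94% in BU+BTT-3033 against Vehicle, and 2-fold changes for 48%, 44% and 58%. When each group had its own spread, 12%, 40% and 30% of the 4-fold changes were recovered. In that simulation, 6 of 27, 20 of 79 and 103 of 144 calls fell on unchanged genes, against 4 of 140, 3 of 115 and 14 of 158 with an equal spread. So adjusted p-values are less reliable in all 3 comparisons where the groups differ in spread, as they did here. The chi-square per degree of freedom between replicates was 5.15 to 23.7 in Vehicle, 6.19 to 46.2 in BU+PBS and 74.5 to 730 in BU+BTT-3033. A simulated list of 25 genes changed 2-fold was called, and 0 of 19 unchanged lists. Simulated genes were drawn independently, so this cannot show how often lists whose members vary together are called without a change.

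Named genes with at least 10% of their exonic bases inside exons of another gene have uncertain counts: on the same strand Insl3 (404 of 623 bases, with Jak3) and Izumo1 (654 of 2992, with Rasip1), and on the opposite strand Oaz3 (2412 of 4326), Sycp3 (660 of 1264), Vwa1 (913 of 3623), Fancd2os (257 of 1359), Ccdc54 (246 of 1298), Uchl1 (295 of 1632), Lipe (918 of 5886) and Ccna2 (510 of 4083). Rps3a2, Rps3a3 and Serpina3h are annotated as pseudogenes, whose reads can come from Rps3a1 and from other Serpina3 genes, and Uba1y has a paralog on the X chromosome.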

Results

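RNA of testis tissue was measured in 9 mouse libraries, 3 per group. The labels name the groups by treatment, Vehicle, BU+PBS and BU+BTT-3033, and call the animals normal and model mice; BU is not spelled out there. BTT-3033 is known as an inhibitor of the collagen receptor integrin α2β1, whose chains are encoded by Itga2 and Itgb1. PBS is a saline buffer. Total counts per library were 46279789 to 50965210 in Vehicle, 43406063 to 49348175 in BU+PBS and 41464437 to 47485605 in BU+BTT-3033. Genes with at least 1 count numbered 29848 ± 195 in Vehicle, 25297 ± 396 in BU+PBS and 28146 ± 1968 in BU+BTT-3033 (SD, n = 3). Transcripts of the mitochondrial genome took 0.938% ± 0.0232 of the counts in Vehicle, 6.13% ± 0.518 in BU+PBS and 5.44% ± 2.08 in BU+BTT-3033 (SD, n = 3).

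BU+BTT-3033 replicate 3 stood apart from the other 2 libraries of its group. Over the 10280 genes at least 2-fold lower in BU+PBS, it lay a median 68.7% of the way from BU+PBS to Vehicle on the log2 scale, against 11.1% for replicate 1 and 9.75% for replicate 2. Its mitochondrial share was 3.33%, against 5.51% and 7.48%. The median log2 fold change of all tested genes was −0.41 in BU+PBS against Vehicle, 0.17 in BU+BTT-3033 against BU+PBS and −0.22 in BU+BTT-3033 against Vehicle. Scaling the libraries to the Sertoli cell list instead of by TMM shifted all log2 fold changes by −3.18, 0.77 and −2.39 in these comparisons. Library size alone shifted them by 0.78, −0.0092 and 0.75, and DESeq2's factors by −0.26, −0.018 and −0.28. List medians are therefore given relative to the median of all genes, and directions of single genes are those under TMM scaling.

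The first comparison, BU+PBS against Vehicle, asks what BU treatment changed in the testis. Several genes of maturing germ cells fell. The protamine gene Prm1, which packs DNA in sperm heads, was at 4871 ± 404 CPM in Vehicle and 0.183 ± 0.0837 CPM in BU+PBS (log2 fold change −14.68, SE 2.45, edgeR adjusted p = 0.0013). Sycp3, of the meiotic chromosome axis, was at 141 ± 3.47 and 1.17 ± 0.626 CPM (−6.92, SE 1.05, adjusted p = 0.000857). Sox9, the Sertoli cell transcription factor, rose from 6.41 ± 0.724 to 122 ± 13 CPM (4.25, SE 0.25, adjusted p = 7.28e-05; n = 3 per group throughout).

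In all, 8555 genes were higher and 11311 lower in BU+PBS, 79.8% of those tested, and 7384 and 10280 of them by at least 2-fold. The 3 libraries of one group all lay above the 3 of the other for 87.6% of genes, where chance gives 10%. That 10% is an average over splits, and genes that vary together can exceed it in a single split. The split between higher and lower calls depended on the scaling: 10986 higher and 9310 lower by library size, and 387 higher and 19694 lower with scaling to the Sertoli cell list.

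All 28 tested members of the meiotic spermatocyte list fell, also adjusted over the list alone. Their median log2 fold change was −7.47 relative to all genes (camera adjusted p = 4.4e-06; adjusted p = 0.436 with an estimated correlation). With genes at 0 in BU+PBS set to their bound the median was −7.27. Rec8, a meiotic cohesin, fell from 127 ± 5.18 to 3.63 ± 1.31 CPM, and Rnf212, a crossover factor, from 6.72 ± 1.53 CPM to 0 counts, at least 123-fold lower. All 22 round spermatid genes fell, also adjusted over the list alone, with a median of −10.5 (camera adjusted p = 3.31e-05; adjusted p = 0.444 with an estimated correlation). Among them were Acr (acrosin of the acrosome), Klhl10 and the transcriptional regulator Crem, with log2 fold changes of −10.82, −8.43 and −4.15. All 19 elongating spermatid genes fell as well, also adjusted over the list alone, with a median of −10.1 (camera adjusted p = 3.74e-05; adjusted p = 0.436 with an estimated correlation). The log2 fold change was −13.52 for Akap4, of the sperm tail's fibrous sheath, and −8.32 for Oaz3, whose exons overlap those of Tdrkh and Mrpl9.

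Among called genes with a mean of at least 5 CPM over all libraries, no overlap between the groups and no clone or predicted name, 8 had the largest fitted falls. Their order, also against Prm1 and Akap4, is not established, since 7 of these folds are lower bounds. Allc (allantoicase), Ccdc54, Ropn1 (of the sperm tail), Gstt4, Gtsf1l, Spata31 and Cylc2 (cylicin, of the sperm head) had 0 counts in all BU+PBS libraries and were at least 13200, 11900, 7920, 7910, 7010, 7010 and 6740-fold lower than in Vehicle. Tnp1, a transition protein of condensing chromatin, had 3 counts in BU+PBS against 2870.1 ± 100.3 CPM in Vehicle, a ratio of 158000 with a counting interval of 54000 to 766000.

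Spermatogonial lists divided. Of 12 differentiating spermatogonia genes 9 fell and 3 rose, also adjusted over the list alone. The list, with a median of −4.25 relative to all genes, did not pass (camera adjusted p = 0.0735; 0.55 with an estimated correlation), but did without BU+PBS replicate 3 (median −8.51, adjusted p = 0.00904). Scml2, a Polycomb protein of germ cells, fell from 17.7 ± 0.968 to 2.4 ± 0.371 CPM and Prss50 from 14.3 ± 1.21 to 0.651 ± 0.243 CPM. The receptor Kit, also known from Leydig cells, rose from 24.3 ± 1.29 to 170 ± 73.1 CPM (log2 fold change 2.81, but −0.31 with scaling to the Sertoli cell list). Of 15 undifferentiated spermatogonia genes 8 fell and 3 rose, also adjusted over the list alone (median −0.99, camera adjusted p = 0.224; 0.436 with an estimated correlation). Gfra1, the GDNF co-receptor of stem spermatogonia, fell from 22.4 ± 2.68 to 0.493 ± 0.381 CPM and Lhx1 was at least 79.5-fold lower. Etv5, also known from Sertoli cells, rose from 19.1 ± 2.63 to 94.4 ± 16.4 CPM (2.31, but −0.91 with scaling to the Sertoli cell list). Of 24 mitotic cell cycle genes 16 fell, including Ccnb1 (log2 fold change −5.23) and Aurkb (−3.10), and 6 rose, including Ccnd2 (3.10, but −0.12 with scaling to the Sertoli cell list). The counts were the same adjusted over the list alone, and the list did not pass (median −0.91, camera adjusted p = 0.0667).

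Somatic lists were higher relative to all genes. Of 24 Sertoli cell genes 22 rose and 0 fell (median 3.79, camera adjusted p = 2.5e-10; adjusted p = 0.406 with an estimated correlation). Fshr, the FSH receptor, rose from 0.968 ± 0.208 to 20.8 ± 0.657 CPM and Rhox8 from 12 ± 1.42 to 92.7 ± 11.7 CPM (log2 fold change 2.95, but −0.26 with scaling to the Sertoli cell list). Of 19 Leydig cell and steroidogenesis genes 18 rose (median 3.34, camera adjusted p = 6.66e-06; adjusted p = 0.426 with an estimated correlation). Among them were Nr5a1 (steroidogenic factor, log2 fold change 3.66), Por (2.31, but −0.86 with scaling to the Sertoli cell list) and Tsc22d3 (1.68, but −1.48). Of 32 extracellular matrix genes 28 rose and 1 fell (median 3.41, camera adjusted p = 1.04e-09; adjusted p = 0.406 with an estimated correlation). They include the proteinase Mmp14 (3.93), biglycan Bgn (3.32) and thrombospondin Thbs1 (3.80). Of 22 inflammatory cytokine and NF-kB genes 19 rose (median 4.28, camera adjusted p = 2.15e-06; adjusted p = 0.427 with an estimated correlation). They include the NF-kB inhibitor Nfkbia (4.21), Relb (3.66) and the chemokine Cxcl10 (4.81). Adjusted over the list alone the counts of these 4 lists were the same except that 1 inflammatory gene fell.

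The counts of higher and lower members were 12 and 1 of 13 for peritubular myoid cells (median 3.08), 11 and 1 of 13 for stromal fibroblasts (3.83), 20 and 2 of 25 for macrophages (3.31) and 14 and 0 of 15 for endothelium (2.60). They were 16 and 3 of 21 for blood-testis barrier junctions (2.35), 17 and 2 of 21 for cholesterol synthesis (2.57) and 16 and 3 of 20 for p53 targets (2.93). For senescence they were 12 and 2 of 14 (3.20, or 3.08 with genes at 0 at their bound) and for the oxidative stress response 13 and 4 of 20 (2.15). The same counts resulted adjusted over the list alone. Each of these 9 lists passed with camera, with the largest adjusted p of 0.00683 for senescence and 0.406 to 0.436 with an estimated correlation. Lymphocyte genes did not pass (5 higher, 4 adjusted over the list alone, and 5 lower of 17, median 0.35, camera adjusted p = 0.87). Among the 5 lower members were the T cell genes Cd3d (13.3 ± 0.299 to 0.233 ± 0.0709 CPM) and Zap70 (6.32 ± 1.54 to 0.811 ± 0.362 CPM). As 5 other members rose, these falls do not show a loss of T cells, and their source cells were not determined. The 5 tested neutrophil and mast cell genes did not pass as a list (3 higher, 1 lower, median 2.85, or 2.53 with genes at 0 at their bound, camera adjusted p = 0.336). Of these Kitl, a ligand that Sertoli cells make, rose from 13.9 ± 2.03 to 183 ± 17.4 CPM. The absolute medians of 16 of the 28 lists changed sign with scaling to the Sertoli cell list, as they did in each of the other 2 comparisons. Of the 19 lists called higher here, 4 then kept a median above 0. The Sertoli cell list itself, whose value (0.193) that scaling holds small, is among these 4.

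Among genes limited in the same way, the largest fitted rises were those of Saa3, an acute phase protein (0.107 ± 0.0997 to 22.7 ± 16.6 CPM; log2 fold change 7.70), and the pseudogenes Rps3a2 (7.19) and Rps3a3 (6.39), whose counts are uncertain. The others were the signalling ligand Wnt4 (7.05), the sodium channel subunit Scn3b (6.52), the water channel Aqp5 (6.06), Clca3a2 (5.84) and Rasgef1c (5.83). Itga2, on chromosome 13 at 114833081 to 114932100 of GRCm38, fell from 14.2 ± 0.76 to 0.798 ± 0.246 CPM (−4.15, SE 0.57, adjusted p = 0.00057). Itgb1, on chromosome 8 at 128685654 to 128733200, rose from 43 ± 2.68 to 380 ± 2.08 CPM (3.14, SE 0.30, adjusted p = 0.000119, but −0.049 with scaling to the Sertoli cell list).

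**Figure D1:**
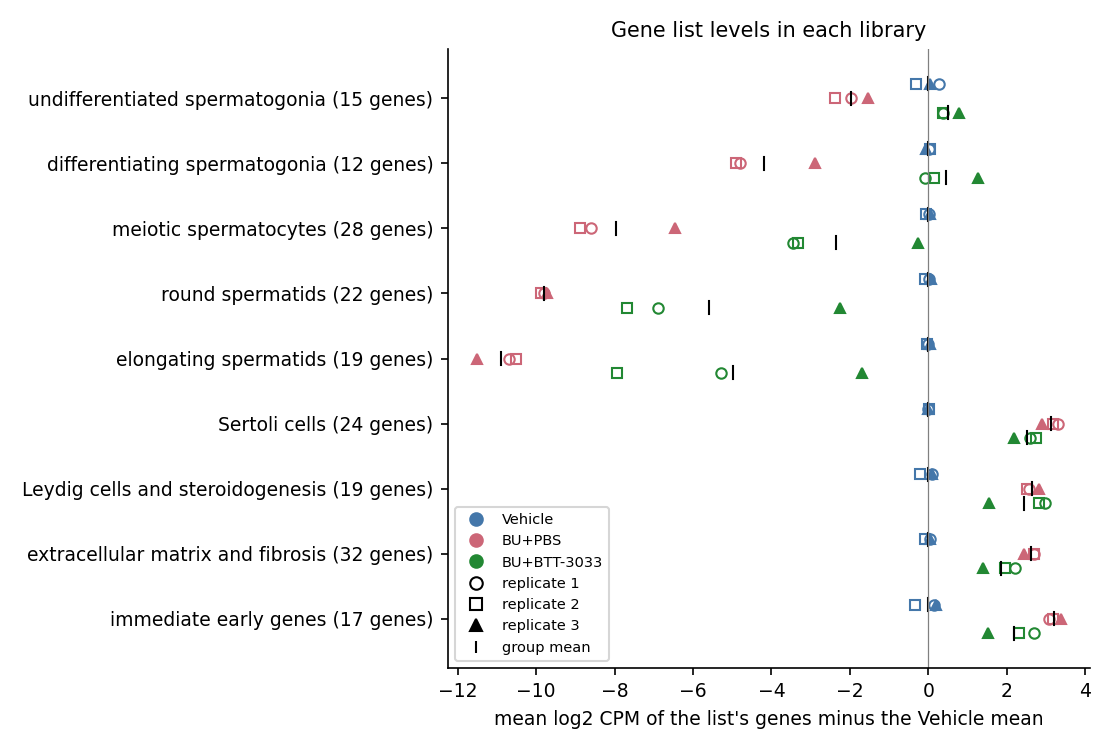
Mean log2 CPM (TMM scaled) of the genes of 9 lists in each library, minus the mean of the 3 Vehicle libraries; points are libraries, marked by replicate, and ticks are group means. The meiotic list lies at −8.59, −8.87 and −6.46 in BU+PBS and at −3.45, −3.33 and −0.27 in BU+BTT-3033, where replicate 3 is the highest; the offsets of the Sertoli cell and other somatic lists depend on the scaling.

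The second comparison, BU+BTT-3033 against BU+PBS, asks what adding BTT-3033 changed in BU-treated testis. Ret and Scml2, of early germ cells, and the proliferation marker Mki67 rose. Ret, the GDNF receptor of stem spermatogonia (chromosome 6, 118151745 to 118197718), went from 0.962 ± 0.117 to 9.75 ± 0.857 CPM (log2 fold change 3.34, SE 0.26, edgeR adjusted p = 0.0204). Scml2 rose from 2.4 ± 0.371 to 33 ± 15.1 CPM (3.78, SE 0.34, adjusted p = 0.0204) and Mki67 from 14.7 ± 1.92 to 58.1 ± 24.5 CPM (1.98, SE 0.28, adjusted p = 0.0383). Gdnf itself, the Sertoli cell factor that signals through Ret (chromosome 15, 7810846 to 7837575), fell from 13.4 ± 1.82 to 4.26 ± 0.964 CPM (−1.66, SE 0.24, adjusted p = 0.0389). Each of these 4 genes differed in the same direction for all 3 libraries against all 3.

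In all, 123 genes were higher and 6 lower, 0.518% of those tested, while 7461 had an unadjusted p under 0.05. The libraries did not overlap for 34.7% of genes. Chance gives 10% on average over splits, but genes that vary together can exceed it in a single split. The count of called genes moved widely with the libraries in the fit and with the threshold (3061 higher and 562 lower at an adjusted p under 0.1). It was 0 without Vehicle replicate 1, 2 or 3 or BU+PBS replicate 1 or 2 (5021 to 6404 genes at an unadjusted p under 0.05), so that each gene named here lost its call there, and 72 and 4 without BU+PBS replicate 3. It was also 0 by edgeR with only the 6 compared samples (4326 at an unadjusted p under 0.05) and with a replicate block (5152). It was 2775 and 291, 3574 and 661, and 2939 and 733 without BU+BTT-3033 replicates 1, 2 and 3. DESeq2, given all 39236 genes, called 2856 and 847, and limma voom, which gave BU+BTT-3033 replicate 3 a weight of 0.0415, 2893 and 1260. Either differs from edgeR in more than the test. Scaling to the Sertoli cell list gave 9893 higher and 16 lower.

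Germ cell lists were higher than other genes. Of 15 undifferentiated spermatogonia genes Ret was called, and 7 rose adjusted over the list alone (median 1.57 relative to all genes, camera adjusted p = 8.9e-06; adjusted p = 0.406 with an estimated correlation). Of 12 differentiating spermatogonia genes Scml2 and Prss50 (0.651 ± 0.243 to 19.7 ± 19 CPM) rose, and 10 adjusted over the list alone (median 5.28, camera adjusted p = 1.66e-08; adjusted p = 0.406 with an estimated correlation). Of 28 meiotic genes edgeR called 0 over all genes, with 28 at an unadjusted p under 0.05, and 28 were higher adjusted over the list alone. DESeq2 called 8 and voom 25 (median 6.35, or 6.26 with genes at 0 at their bound, camera adjusted p = 3.71e-13; adjusted p = 0.406 with an estimated correlation). The round spermatid list (median 7.17, or 6.95 at the bound) had 0 of 22 called by edgeR, 20 adjusted over the list alone, 21 at an unadjusted p under 0.05, 2 by DESeq2 and 11 by voom (camera adjusted p = 2.96e-06; adjusted p = 0.436 with an estimated correlation). For the elongating spermatid list (median 7.20) these counts were 0, 19, 19, 4 and 17 of 19 (camera adjusted p = 6.78e-08; adjusted p = 0.426 with an estimated correlation). The most abundant members, Ldhc (1.47 ± 2.15 to 576 ± 877 CPM), Tssk2 (0.382 ± 0.202 to 69.5 ± 102 CPM) and Prm2 (3.14 ± 2.12 to 1091 ± 1677 CPM), had adjusted p of 0.0687, 0.0645 and 0.0667, with replicate 3 holding most of the mean. Without BU+BTT-3033 replicate 3 the round spermatid median was 3.79. The undifferentiated median was 2.54 without BU+PBS replicate 1 and 2.47 without BU+BTT-3033 replicate 1, and the differentiating one 9.64 without BU+PBS replicate 3. Without BU+BTT-3033 replicate 1, 2 or 3 these 3 genes passed (0.0392, 0.0353 and 0.0207 for Ldhc, 0.0376, 0.0226 and 0.0114 for Tssk2, 0.0424, 0.025 and 0.0252 for Prm2).

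In replicate 3 the meiotic and spermatid lists lay nearer to Vehicle than in replicates 1 and 2, and the 2 spermatogonia lists were at their highest. Relative to the Vehicle mean, round spermatid genes were at −6.88, −7.67 and −2.24 log2 units in BU+BTT-3033 replicates 1, 2 and 3, against −9.79, −9.87 and −9.71 in BU+PBS, and differentiating spermatogonia genes at −0.08, 0.15 and 1.27, against −4.79, −4.90 and −2.89. Mitotic cell cycle genes were also higher: 3 of 24 rose, Ccna2 (2.04), Mki67 and Mcm2 (1.29), and 17 adjusted over the list alone (median 1.79, or 1.18 without BU+BTT-3033 replicate 3, camera adjusted p = 3.16e-08; adjusted p = 0.406 with an estimated correlation).

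Somatic lists were lower relative to all genes, which include the germ cell genes that were higher, with few called members. Absolute medians with scaling to the Sertoli cell list were −0.0545 for extracellular matrix and −0.0911 for stromal fibroblasts. They were −0.0205 for myoid cells and −0.323 for inflammatory genes. Those of the other lists in this paragraph and the next were then 0.124 (Sertoli cells) to 0.619 (endothelium). The Sertoli cell value is held small by that scaling itself. Gdnf was the 1 of 24 Sertoli cell genes that fell, with 9 lower and 1 higher adjusted over the list alone (median −0.81, camera adjusted p = 1.13e-08; adjusted p = 0.406 with an estimated correlation). The list lay at 2.59, 2.75 and 2.18 in BU+BTT-3033 replicates 1, 2 and 3 and at 3.30, 3.19 and 2.90 in BU+PBS, relative to the Vehicle mean. In the extracellular matrix list (median −0.98, camera adjusted p = 1.17e-12; adjusted p = 0.406 with an estimated correlation) fibronectin Fn1 went the other way and rose from 19 ± 2.78 to 53.9 ± 10.8 CPM (1.51, SE 0.18, adjusted p = 0.0326). Of the 32 members 20 were lower adjusted over the list alone. In the senescence list (median −0.57, camera adjusted p = 0.0283; adjusted p = 0.406 with an estimated correlation; −0.85 and −0.89 without BU+BTT-3033 replicates 1 and 2, and −0.21 with adjusted p = 0.157 without replicate 3) Cdkn2a, a cell cycle inhibitor, rose from 0.348 ± 0.23 to 5.8 ± 1.75 CPM. Inflammatory genes had a median of −1.22 (camera adjusted p = 4.23e-09; adjusted p = 0.406 with an estimated correlation). Relative to the BU+PBS mean the list lay at −0.47, −0.82 and −2.02 in BU+BTT-3033 replicates 1, 2 and 3. Without replicate 3 the medians were −0.73 for this list, −0.46 for Sertoli cells and −0.56 for extracellular matrix, and all 3 passed (largest adjusted p = 2e-06). Of 22 inflammatory members 0 were called by edgeR, with 12 lower at an unadjusted p under 0.05, 6 lower adjusted over the list alone, 7 lower by DESeq2, and 11 lower and 1 higher by voom. The most abundant member, Vcam1, was at 656 ± 5.25 and 735 ± 403 CPM (0.16, adjusted p = 0.823, and −0.044 and −0.12 without BU+BTT-3033 replicates 1 and 2; 0.56 and adjusted p = 0.00459 without replicate 3).

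The lists of stromal fibroblasts (median −1.08, 7 of 13 lower adjusted over the list alone), peritubular myoid cells (−0.95, 9 of 13), blood-testis barrier junctions (−0.78, 11 lower and 2 higher of 21), macrophages (−0.52, 0 of 25) and lymphocytes (−0.70, 1 of 17) also passed with camera. So did those of endothelium (−0.29, 0 of 15), p53 targets (−0.66, 1 of 20), cholesterol synthesis (−0.30, 0 of 21) and the oxidative stress response (−0.40, 0 of 20). Their camera adjusted p ranged from 2.77e-07 to 0.0373, and from 0.406 to 0.597 with an estimated correlation. None of their members was called by edgeR over all genes, and at an unadjusted p under 0.05 the lower members numbered 7, 10, 12, 0, 1, 1, 4, 2 and 3 and the higher ones 0, 0, 3, 1, 1, 0, 0, 0 and 0. DESeq2 called 6, 6, 6, 0, 1, 0, 2, 1 and 1 lower and 1 junction gene higher. Limma voom called 7, 9, 13, 0, 1, 0, 3, 2 and 3 lower, and 2 junction genes, 2 macrophage genes, 1 p53 target and 1 cholesterol synthesis gene higher. The macrophage list thus had no member called lower by any of these. Dcn (decorin, 827 ± 61.9 to 354 ± 126 CPM), Acta2 (smooth muscle actin, 431 ± 63.2 to 203 ± 54.8 CPM) and Cldn11 (551 ± 54.7 to 307 ± 118 CPM) had adjusted p of 0.0665, 0.0666 and 0.115. Dcn and Acta2 passed without BU+BTT-3033 replicate 1 (0.0357 and 0.0388) or 3 (0.0125 and 0.0137), and Cldn11 without replicate 2 (0.0357) or 3 (0.0314). Leydig cell genes did not pass (median −0.30, camera adjusted p = 0.115), and Insl3, a Leydig cell hormone, was at 9530.1 ± 853 and 6305 ± 3595 CPM (−0.60, adjusted p = 0.456, but 0.11 with scaling to the Sertoli cell list). Lyz2, of macrophages, was at 372 ± 17.1 and 229 ± 144 CPM (−0.70, adjusted p = 0.293, but 0.022 with that scaling). Without BU+BTT-3033 replicate 3 the medians of the Leydig, cholesterol, endothelium, oxidative stress and macrophage lists were 0.24, 0.17, 0.0048, 0.0029 and −0.018, and none passed (camera adjusted p = 0.319, 0.504, 0.527, 0.0643 and 0.367). Those of junctions, myoid cells, lymphocytes and p53 targets were then −0.48, −0.53, −0.36 and −0.28, and passed. Without BU+BTT-3033 replicates 1 and 2 the medians were −0.54 and −0.47 for cholesterol synthesis and −0.45 and −0.49 for endothelium, and without replicate 1 −1.07 for macrophages. The Leydig list passed without BU+BTT-3033 replicate 1 or 2 (adjusted p = 0.00417 and 0.0257). Calls were also lost for cholesterol synthesis without BU+PBS replicate 2 (0.0617), for macrophages without BU+PBS replicate 3 (0.0803), and for lymphocytes without BU+PBS replicates 1 and 2 and BU+BTT-3033 replicate 2 (0.0706, 0.0563 and 0.0684).

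With the same limits on abundance, overlap and names, the largest fitted rises were those of Camkv, with 0 counts in BU+PBS and 4.06 ± 1.82 CPM in BU+BTT-3033, at least 74.2-fold higher, and the meiotic genes Ankrd31 (log2 fold change 6.49) and M1ap (6.20). The others were the germ cell ATP carrier Slc25a31 (6.24), Brsk2 (5.93), the germ cell transcription factor Taf7l (5.76), Prss50 (4.91) and Uba1y on the Y chromosome (4.75, from 0.51 ± 0.245 to 13.8 ± 6.4 CPM). Besides Gdnf, the genes called lower were Vwa1, an extracellular matrix protein (−1.19), Noct (−1.04), Ppm1l (−0.96), Ddit4l (−0.88) and Lpar1, a lysophosphatidic acid receptor (−0.80), with adjusted p of 0.0331 to 0.0487. Itga2 was at 0.798 ± 0.246 and 0.924 ± 0.701 CPM (0.21, SE 0.51, adjusted p = 0.804; −0.60 without BU+BTT-3033 replicate 3). Itgb1 was at 380 ± 2.08 and 280 ± 101 CPM (−0.44, SE 0.27, adjusted p = 0.294, but 0.29 with scaling to the Sertoli cell list).

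**Figure D2:**
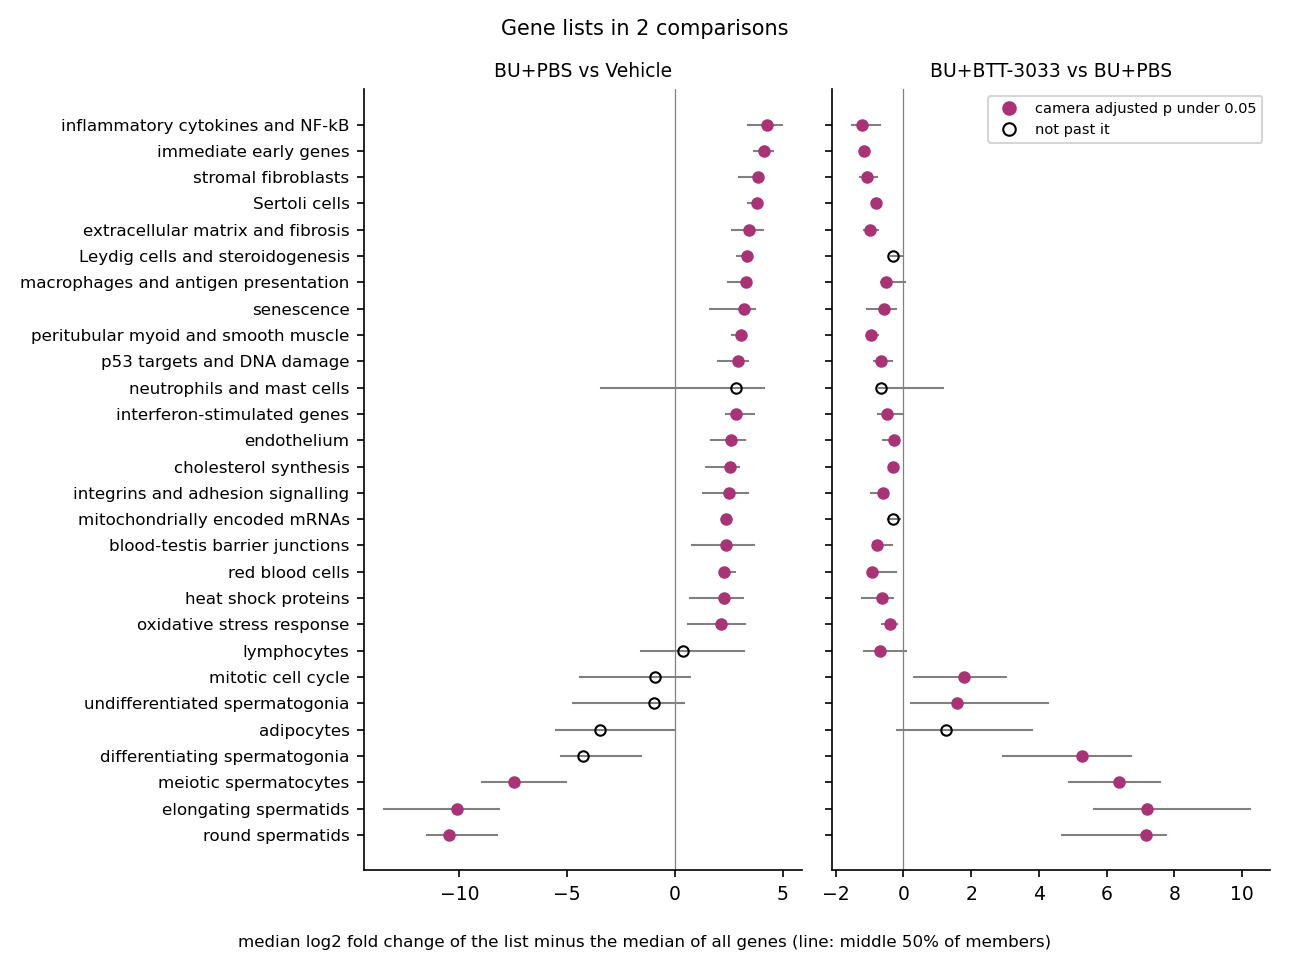
Median log2 fold change of 28 gene lists minus the median of all tested genes, for BU+PBS against Vehicle (left) and BU+BTT-3033 against BU+PBS (right); lines span the middle 50% of the members and filled points passed camera at an adjusted p under 0.05. The elongating spermatid list lies at −10.1 on the left and 7.20 on the right, and the Sertoli cell list at 3.79 and −0.81; 0 lists passed with an estimated correlation.

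Across genes, the log2 fold changes of the second comparison ran against those of the first (Pearson r = −0.913, Spearman rho = −0.871 over 24894 genes, which are not independent replicates). Unchanged groups simulated against the shared BU+PBS libraries gave r of −0.286 on average and −0.309 at the lowest, and a covariance of −0.095 against −11.8 observed, a difference of −11.7. In these simulations all 3 groups had the mean levels of BU+PBS, and genes were drawn independently. They therefore do not show what r would arise with BU acting and germ cell genes varying together between samples. Of the genes lower in BU+PBS than in Vehicle, 114 were called higher in BU+BTT-3033, where independent lists would share 55.9. Another 5 were higher and then lower (2.06 for independent lists) and 3 were called in the same direction in both, against 45. With 3 BU+PBS libraries the shared group could not be divided into parts of at least 2, so part of the excess may come from the shared libraries. Genes near the floor in BU+PBS also could not be called lower again, which the numbers for independent lists do not take into account. The r of the single BU+BTT-3033 replicates 1, 2 and 3 was −0.63, −0.57 and −0.94, and the r without replicate 3 was −0.62.

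The third comparison, BU+BTT-3033 against Vehicle, asks how far the treated testis still differed from normal. The spermatid gene Crem was lower and the Sertoli cell gene Sox9 higher: Crem was at 42.9 ± 41.1 CPM against 327 ± 9.51 CPM in Vehicle (log2 fold change −2.93, SE 0.62, edgeR adjusted p = 0.00555), and Sox9 at 64.1 ± 18.6 against 6.41 ± 0.724 CPM (3.32, SE 0.24, adjusted p = 0.000195). Ret was above Vehicle at 9.75 ± 0.857 against 2.53 ± 0.44 CPM (1.95, SE 0.25, adjusted p = 0.000546, but −0.46 with scaling to the Sertoli cell list).

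There were 7871 genes higher and 5740 lower, 54.7% of those tested, and the libraries did not overlap for 77.8% (chance gives 10% on average over splits). Fewer or more were lower when single libraries were left out: 11589 without BU+BTT-3033 replicate 3, and 3806 and 3734 without Vehicle replicates 1 and 3. Scaling to the Sertoli cell list gave 377 higher and 17451 lower, library size 10692 and 2829, and DESeq2's size factors 6888 and 7455. Limma voom called 11254 lower.

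Of 22 round spermatid genes 7 fell, Spaca1 and Izumo1, the sperm protein that binds the egg, among them (log2 fold changes −3.94 and −4.14). Izumo1, and Meig1 and Odf2 below, lost their calls without each Vehicle library, among others (adjusted p of 0.0607 to 0.0908). Adjusted over the list alone 1 fell (median −3.70 relative to all genes, camera adjusted p = 7.98e-05; adjusted p = 0.436 with an estimated correlation). Of 19 elongating spermatid genes Meig1 (−3.20) and Odf2 (−3.01) fell, and 0 adjusted over the list alone by edgeR (median −2.87, camera adjusted p = 0.000487; adjusted p = 0.45 with an estimated correlation). These medians rested on BU+BTT-3033 replicate 3: without it they were −6.91 and −5.87 (camera adjusted p = 2.87e-09 and 0.00601), with Spaca1 at −6.26, Izumo1 at −7.56, Meig1 at −5.95 and Odf2 at −5.58. Elongating spermatid genes lay at −5.28, −7.94 and −1.69 relative to the Vehicle mean in replicates 1, 2 and 3, and round spermatid genes at −6.88, −7.67 and −2.24. Of 28 meiotic genes Rec8 fell (−3.15), and 0 adjusted over the list alone by edgeR (median −1.14, camera adjusted p = 0.0199; adjusted p = 0.613 with an estimated correlation), and the list did not pass without BU+BTT-3033 replicate 1 or 2 (medians −0.67 and −0.68, 0.0565 and 0.0589). Without replicate 3 its median was −2.72 (0.0496), and it lay at −3.45, −3.33 and −0.27 in the 3 libraries. Spermatogonial lists did not pass. Of 12 differentiating genes 4 rose, 3 adjusted over the list alone (median 1.23, camera adjusted p = 0.221). Among them were Kit (2.86), Dnmt3b (1.86, but −0.52 with scaling to the Sertoli cell list) and Uchl1 (1.31, but −1.08). Of 15 undifferentiated genes 4 rose and 2 fell, also adjusted over the list alone (median 0.56, camera adjusted p = 0.325), with Zbtb16 at 2.63 and Etv5 at 2.14 (−0.30 with that scaling). Of 24 mitotic cell cycle genes 8 rose, including Ccnd2 (2.70) and the replication factors Mcm2 (2.19, but −0.22) and Mcm4 (1.75, but −0.65), and 6 fell (camera adjusted p = 0.87).

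Of 24 Sertoli cell genes 22 rose, with Rhox8 at 2.44 and Dmrt1 at 1.97 (−0.43 with scaling to the Sertoli cell list; median of the list 2.88, camera adjusted p = 2.72e-10; adjusted p = 0.406 with an estimated correlation). Of 19 Leydig cell genes 18 rose, including Nr5a1 (3.11), Tsc22d3 (2.07, but −0.34) and Por (1.97, but −0.47; median 3.02, camera adjusted p = 2.15e-06; adjusted p = 0.426 with an estimated correlation). Of 32 extracellular matrix genes 29 rose and 2 fell, including Mmp14 (2.98), Thbs1 (2.79) and laminin Lamb1 (2.86; median 2.40, camera adjusted p = 2.36e-08; adjusted p = 0.406 with an estimated correlation). Of 22 inflammatory genes 18 rose and 1 fell, including Cxcl10 (3.88), Nfkbia (3.05) and Relb (2.66; median 3.03, camera adjusted p = 4.91e-05; adjusted p = 0.436 with an estimated correlation). Adjusted over the list alone the counts of these 4 lists were the same. The lists of macrophages (median 2.73, 21 of 25 higher), endothelium (2.31, 14 of 15) and stromal fibroblasts (2.63, 11 of 13) passed as well. So did those of peritubular myoid cells (2.10, 11 of 13), blood-testis barrier junctions (1.46, 14 of 21), cholesterol synthesis (2.02, 16 of 21), p53 targets (2.14, 15 of 20), senescence (2.37, 9 of 14) and the oxidative stress response (1.93, 12 of 20). Members that fell numbered 2 for macrophages, 2 for stromal fibroblasts, 1 for myoid cells, 3 for junctions, 1 for cholesterol synthesis, 3 for p53 targets, 1 for senescence and 4 for oxidative stress. Adjusted over the list alone these were the same, except 2 for cholesterol synthesis. Camera adjusted p was 6.7e-05 to 0.0106 for these 9 lists, and 0.406 to 0.45 with an estimated correlation. Adjusted over the list alone, 23, 14, 11, 12, 14, 17, 15, 9 and 13 of their members were higher. Lymphocyte genes (median −0.55, camera adjusted p = 0.445) and neutrophil and mast cell genes (2.17, or 0.36 with genes at 0 at their bound; camera adjusted p = 0.608) did not pass.

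With these limits the largest fitted rises were those of Rps3a2 (7.84), Wnt4 (5.65), Aqp5 (5.33), Scn3b (5.28) and Lrg1, a secreted glycoprotein (5.16). The others were Serpina3h (4.86) and Serpina3g (4.72), which share a family, and Igfbp3, an insulin-like growth factor binding protein (4.71). The largest fitted falls were those of the long non-coding BB019430, with 3 counts in BU+BTT-3033 and a ratio of 861 (counting interval 295 to 4180), and Apol7b (−5.14), Stpg1 (−4.64) and Mdga2 (−4.58). The others were Pitpnm2os1 (−4.53), the transcription factor gene Six2 (−4.48), Fam24a (−4.46) and Fancd2os (−4.41). Without each Vehicle library, among others, Apol7b, Stpg1, Six2, Fam24a and Fancd2os lost their calls (adjusted p of 0.0563 to 0.0855). Without BU+BTT-3033 replicate 3 these 5 genes were at −9.16, −7.84, −7.04, −7.83 and −8.40, and Pitpnm2os1 at −7.33. Itga2 was at 0.924 ± 0.701 against 14.2 ± 0.76 CPM (−3.94, SE 0.57, adjusted p = 0.00097) and Itgb1 at 280 ± 101 against 43 ± 2.68 CPM (2.70, SE 0.29, adjusted p = 0.000318).

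**Figure D3:**
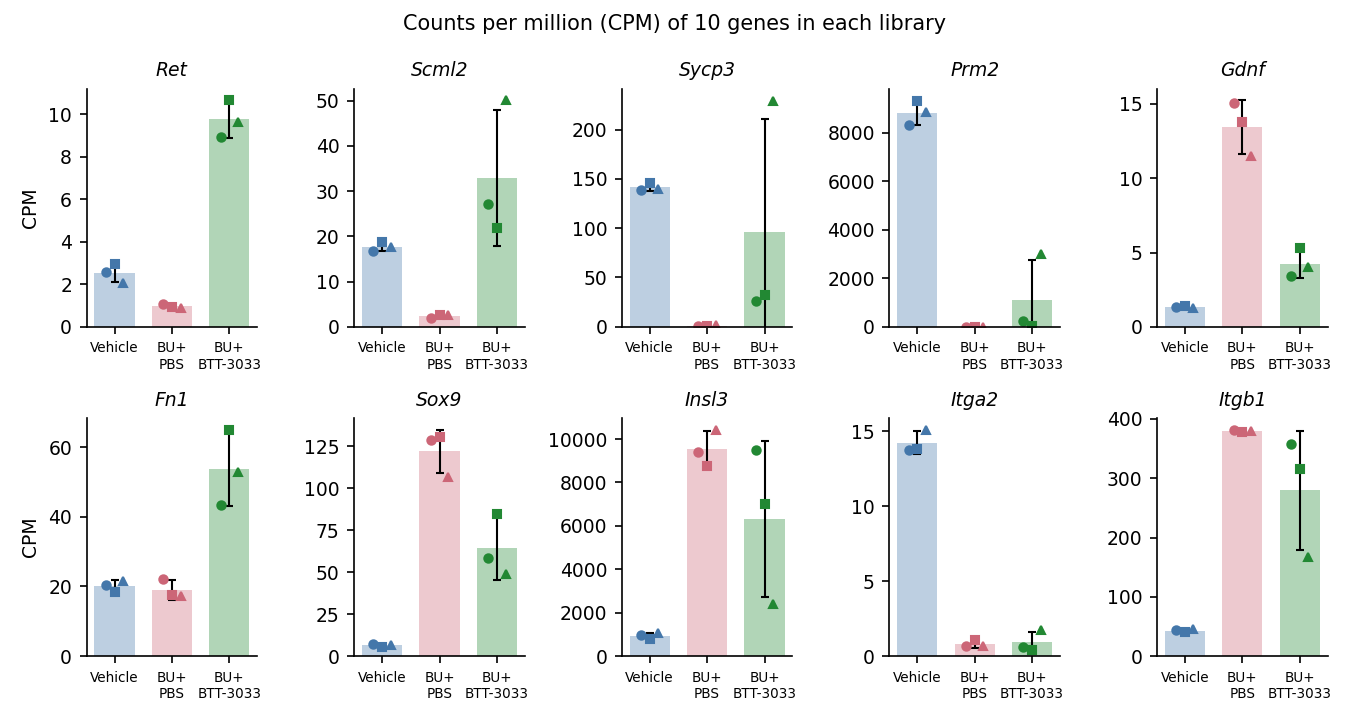
CPM (TMM scaled) of 10 genes in each library, chosen from those named in the text; bars are group means from 0, error bars SD (n = 3) and points libraries, marked by replicate. Ret reaches 9.75 CPM in BU+BTT-3033 against 0.962 in BU+PBS and 2.53 in Vehicle, Itga2 stays at 0.798 and 0.924 CPM in the BU groups against 14.2 in Vehicle, and Itgb1 is highest in BU+PBS at 380 CPM, a rise over Vehicle that scaling to the Sertoli cell list takes to −0.049 on the log2 scale.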

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

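The alternative of an adjusted p under 0.1 was chosen after the data were seen; the others were planned. The counts of BU+BTT-3033 against BU+PBS rest on the setting most. List values under the alternatives were taken relative to the median of all genes, and gene values limited to the genes named, after first results were seen. Except where its construction shows it, the cause of a change was not tested.

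Scaling to the Sertoli cell list gave 387 higher and 19694 lower genes in BU+PBS against Vehicle (8555 and 11311 by TMM), 9893 and 16 in BU+BTT-3033 against BU+PBS (123 and 6), 377 and 17451 in BU+BTT-3033 against Vehicle (7871 and 5740), 9860 genes called in opposite directions (119) and 14 lists in BU+PBS against Vehicle (22). That scaling moves every gene by the shifts given above. With it, log2 fold changes turned to −0.049 (Itgb1), −0.91 (Etv5), −0.31 (Kit), −0.26 (Rhox8), −1.48 (Tsc22d3), −0.86 (Por) and −0.12 (Ccnd2) in BU+PBS against Vehicle, to 0.29 (Itgb1), 0.11 (Insl3) and 0.022 (Lyz2) in BU+BTT-3033 against BU+PBS, and to −0.30 (Etv5), −0.46 (Ret), −0.52 (Dnmt3b), −1.08 (Uchl1), −0.43 (Dmrt1), −0.34 (Tsc22d3), −0.47 (Por), −0.22 (Mcm2) and −0.65 (Mcm4) in BU+BTT-3033 against Vehicle. Library size gave 373 and 13 genes in BU+BTT-3033 against BU+PBS, 2829 lower in BU+BTT-3033 against Vehicle and 333 in opposite directions.

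In BU+BTT-3033 against BU+PBS the DESeq2 Wald test called 2856 and 847 genes, voom 2893 and 1260 and an adjusted p under 0.1 gave 3061 and 562; in opposite directions these gave 3355, 3770 and 3429. Without a low-count filter 2 genes were lower, and with at least 2-fold 3. With only the 6 samples compared, edgeR called 0 higher, 0 lower and 0 in opposite directions (4326 at an unadjusted p under 0.05). Whether the replicate numbers pair the samples is not settled. Deviations from the group mean correlated at −0.0106 to 0.0974 between same-numbered libraries of different groups, and at −0.0974 to 0.0566 between others. Same-numbered BU+PBS and BU+BTT-3033 libraries were at 0.0756, 0.0264 and 0.0974 for replicates 1, 2 and 3. A replicate block gave 0 higher, 0 lower and 0 in opposite directions (5152 unadjusted). Voom called 11254 genes lower in BU+BTT-3033 against Vehicle. The correlation of fold changes was −0.8174 with the Wald test, −0.675 with voom and −0.7981 without a filter. With the list correlation estimated, 0 lists passed in each comparison (1, 4 and 0 at an unadjusted p under 0.05; fry 27, 16 and 23). Lymphocyte medians turned to −1.27 and 0.11 in the first 2 comparisons with at least 1 CPM in 3 libraries, and Itga2 to −0.59 with voom in BU+BTT-3033 against BU+PBS.

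Leaving out each library in turn gave 7932 to 9226 higher and 10566 to 12357 lower genes in BU+PBS against Vehicle, 0 to 3574 and 0 to 733 in BU+BTT-3033 against BU+PBS, 7057 to 8959 and 3734 to 11589 in BU+BTT-3033 against Vehicle, 0 to 4110 in opposite directions, a correlation of −0.9073 to −0.6238 and 21 to 23, 18 to 26 and 19 to 20 lists. In BU+BTT-3033 against BU+PBS, medians ran from −0.53 to 0.24 (Leydig cells and steroidogenesis), −0.54 to 0.17 (cholesterol synthesis), −1.01 to 0.66 (neutrophils and mast cells), −0.49 to 0.0048 (endothelium) and −0.60 to 0.0029 (oxidative stress response), and log2 fold changes from −0.60 to 0.55 (Itga2) and −0.12 to 0.56 (Vcam1).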

Other observations

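All tests of explanations in this part were chosen after the result was seen, except those of other splits of the samples. Immediate early genes, which respond quickly to stimuli, were higher in BU+PBS than in Vehicle for 15 of 17 members, with 1 lower (median log2 fold change 4.13 relative to all genes, camera adjusted p = 2.96e-06; adjusted p = 0.426 with an estimated correlation). Egr2 rose from 1.35 ± 0.585 to 55.5 ± 3.94 CPM, Nr4a2 from 3.09 ± 0.0561 to 35.8 ± 5.12 CPM and Ier2 from 23.5 ± 2.51 to 305 ± 34 CPM. In BU+BTT-3033 the list lay below BU+PBS (median −1.17, or −0.76 without BU+BTT-3033 replicate 3, camera adjusted p = 2.5e-10; adjusted p = 0.406 with an estimated correlation), with 15 members lower adjusted over the list alone, 0 called by edgeR over all genes, 15 at an unadjusted p under 0.05, 5 by DESeq2 and 13 by voom. Its most abundant member, Egr1, was at 1903 ± 149 and 914 ± 397 CPM (−1.06, adjusted p = 0.126, and 0.0486 without BU+BTT-3033 replicate 3). Interferon-stimulated genes were higher in BU+PBS than in Vehicle for 19 of 24 members and lower for 2 (median 2.83, camera adjusted p = 6.7e-05; adjusted p = 0.435 with an estimated correlation), and lower in BU+BTT-3033 than in BU+PBS as a list (−0.49, camera adjusted p = 0.00741; adjusted p = 0.471 with an estimated correlation). That call rested on BU+BTT-3033 replicate 3: the list lay 0.16 and 0.013 above the BU+PBS mean in replicates 1 and 2 and at −1.05 in replicate 3, and without it the median was −0.033 (adjusted p = 0.314). Integrin and adhesion genes were higher for 20 of 25 members and lower for 4 in the first of these comparisons (2.51, camera adjusted p = 4.27e-05; adjusted p = 0.406 with an estimated correlation) and lower as a list in the second (−0.61, or −0.37 without BU+BTT-3033 replicate 3, camera adjusted p = 3.56e-06; adjusted p = 0.406 with an estimated correlation). In BU+BTT-3033 against BU+PBS, scaling to the Sertoli cell list gave absolute medians of −0.286 for immediate early genes. It gave 0.384 for interferon-stimulated genes and 0.294 for integrin and adhesion genes. In BU+PBS against Vehicle that scaling gave 0.561 for immediate early genes, −0.752 for interferon-stimulated genes and −1.1 for integrin and adhesion genes.

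Heat shock genes (9 of 12 higher, 3 lower; median 2.26, camera adjusted p = 0.0313), red blood cell genes (5 of 7 higher, 1 lower; 2.28, or 2.19 with genes at 0 at their bound, camera adjusted p = 0.0262) and mitochondrially encoded mRNAs (13 of 13 higher; 2.38, camera adjusted p = 0.000144) were also above Vehicle in BU+PBS (adjusted p = 0.406, 0.406 and 0.436 with an estimated correlation). The red blood cell call was lost without BU+BTT-3033 replicate 3 (adjusted p = 0.158). In BU+BTT-3033 against BU+PBS the medians of these 3 lists were −0.63, −0.92 and −0.32, of which the last did not pass (camera adjusted p = 0.000459, 0.000288 and 0.17; 0.406, 0.406 and 0.673 with an estimated correlation), though it did without BU+BTT-3033 replicate 2 (adjusted p = 0.00256). Without replicate 3 the first was −0.41. With scaling to the Sertoli cell list the absolute medians of these 3 lists were −1.29, −1.35 and −1.23 in BU+PBS against Vehicle. They were 0.304, 0.0623 and 0.615 in BU+BTT-3033 against BU+PBS, so their directions depended on the scaling. Adipocyte genes did not pass in BU+PBS against Vehicle (6 tested, camera adjusted p = 0.347). Among them Lipe (797 ± 32 to 25.1 ± 3.76 CPM) and Pnpla2 (407 ± 14 to 59.6 ± 4.17 CPM), both lipases, fell. So did Cst8 (264 ± 17.3 to 16.1 ± 6.19 CPM) of the epididymis list, which had too few tested members for a list test. The source cells of these transcripts were not determined. By chromosome, 120 of 137 tested Y-linked genes were lower in BU+PBS than in Vehicle and 8 higher (median log2 fold change −7.59), while of 980 X-linked genes 485 were higher and 367 lower (1.06), against −0.40 for the median of autosomal genes. Of 4014 long non-coding genes 2509 were lower and 626 higher (−4.28, against 0.06 for protein-coding genes). Long non-coding genes took 2.70 to 2.84% of the CPM of tested genes in Vehicle, 0.867 to 0.905% in BU+PBS and 1.05, 0.992 and 1.78% in BU+BTT-3033 replicates 1, 2 and 3.

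With 3 libraries against 3 there are 10 splits of the compared samples, too few for a share under 0.05. In the fit of 9 libraries the real split was the 1 of 10 with the most genes called in each comparison: 19866, 129 and 13611 genes, against 0 at the highest of the other splits. Every other split puts libraries of both groups on each side, so a difference between the groups widens the spread within the sides. Few calls are then left for those splits, and these counts decide nothing. The splits were first run with the 6 compared libraries alone, which gave 20847, 0 and 11322 genes for the real splits and 0 for the others, and then in the fit of 9 libraries. In that first run the real split of BU+BTT-3033 against BU+PBS thus called no more genes than the others.

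The first pattern is the higher level of somatic cell lists in BU+PBS than in Vehicle. Loss of germ cell RNA alone would raise every other cell type alike, and the medians of 6 somatic cell lists ran from 2.60 for endothelium to 3.83 for stromal fibroblasts relative to all genes, further apart than members exchanged between lists (permutation p = 0.0085, 10000 permutations). Genes of a list are not independent replicates, and none of these lists passed with an estimated correlation, so this p may be too small and the explanation stays open. The test left out the lists of lymphocytes (0.35), adipocytes (−3.47), red blood cells (2.28) and neutrophils and mast cells (2.85). The choice of scaling stays open: scaling to the Sertoli cell list moved all genes by about the same −3.18, so that 4 of 19 lists called higher kept a median above 0 follows from that shift and decides nothing. With library size and with DESeq2 size factors 19 of 19 did. A change of expression within these cells through BU stays open and was not tested.

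The second pattern is BU+BTT-3033 replicate 3, which lay apart from the other 2 libraries of its group. A Vehicle library under a wrong label is argued against by the genes higher in BU+PBS, over which it lay 39.2% of the way to Vehicle, where the lowest Vehicle library lay at 99%. A mixture of Vehicle RNA with RNA of a BU library is argued against by 21.9% of 96 germ cell list genes, which were at least 1.5-fold above all 8 other libraries (1.04% at most in another library): 12 of 28 meiotic, 5 of 12 differentiating and 4 of 15 undifferentiated spermatogonia genes, and 0 of 22 round and 0 of 19 elongating spermatid genes. A stronger response of this sample to BTT-3033, a weaker response to BU and a label exchanged with a sample outside this series may each be the cause and were not tested.

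The third pattern is the germ cell genes above BU+PBS in BU+BTT-3033 replicates 1 and 2. Carry-over of RNA from Vehicle libraries would bring all germ cell lists in about the same share, and the highest list share was 138 times the lowest or more; for carry-over from BU+BTT-3033 replicate 3 it was 25.7 times or more, so both are argued against as the whole cause. BU+PBS mice differing in how many germ cells survive cannot be told apart from an effect of BTT-3033 with 3 samples per group. On the log2 scale, BU+PBS replicate 3 lay above the other 2 by 43% of the gap to the lowest BU+BTT-3033 library on the meiotic list, 25.6% and 41.1% on the undifferentiated and differentiating spermatogonia lists and 5.4% on the round spermatid list. On the elongating spermatid list BU+PBS replicate 2 was the highest, by 19.5%. As a share of the Vehicle level, the meiotic list was at 0.259%, 0.214% and 1.14% in BU+PBS replicates 1, 2 and 3. It was at 9.18% in BU+BTT-3033 replicate 1, the lowest of its group. These 2 carry-over tests were first run on TMM-scaled CPM, as was that of a mixture, and moved to unscaled CPM with the same outcome. That BTT-3033 may leave more germ cells after BU is therefore a hypothesis, which these data do not decide; germ cell counts in testis sections of more animals per group would bear on it.

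A further hypothesis is an excess of X-linked genes over the autosomes among those called higher in BU+BTT-3033 than in BU+PBS. With edgeR 21 of 980 X-linked genes were called higher (2.14%) against 100 of 23109 autosomal genes (0.433%), an odds ratio of 5.04 (95% interval 2.97 to 8.17, Fisher's exact p = 1.81e-08). The odds ratio was 1.78 with DESeq2 (exact p = 1.66e-10), 1.25 with voom (exact p = 0.0193) and 1.02 with edgeR without BU+BTT-3033 replicate 3 (exact p = 0.801). Genes are not independent replicates, so these p-values may be too small, and the excess stays open.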
